A study of Mus musculus with 4 samples.

How the data were processed

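Total RNA was taken, per the labels' protocols, from freshly sorted YFP-positive satellite cells with a column kit (RNeasy Mini), labelled with biotin by the GeneChip small sample labelling assay version II and hybridised to 1 array per sample. The titles call the 2 samples of each group biological replicates; how many mice each pooled is not given in the sources used here. The deposited values are linear MAS5 signal intensities, 1 per probe set and array, per the submitters' processing notes. MAS5 combines matched and mismatched probes into 1 intensity and can scale each array as a whole, which removes differences of overall brightness and no others. Its scaling target is not given in the sources used here. The 2% trimmed means of the deposited arrays were 230 and 238 for control and 240 and 211 for cKO, so the arrays were not at 1 common mean, and the overall level is left open by about that much. Detection calls and scanner files were not used here.

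Gene names came from the platform's annotation. Of 45101 probe sets, 64 were AFFX controls, 34945 had 1 gene symbol, 932 several and 9160 none. Entrez identifiers were looked up in the mouse gene table supplied, where 34754 probe sets were found, and 0 symbols changed. No gene was named from a probe set with several symbols. In all, 18193 genes were named. No coordinates are given, since no genome build belongs to these values.

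Values were analysed as log2(value + 1) without further normalization; fold changes are on this scale and understate changes of low signals, while means and SDs are of the signals. AFFX probe sets were left out, and probe sets were kept when their mean log2 value over all 4 arrays reached the median of all probe sets (a signal of 63.9), which left 22519 probe sets, 19192 of them with 1 symbol. For genes with several kept probe sets the brightest was used, giving 10140 genes. Other kept probe sets of a gene did not always share its sign, as for Ccn1, Klf4, Yap1, Dnajc3, Nr4a2 and Pde10a. The cKO and control groups were compared with limma version 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with no block, and Benjamini-Hochberg adjustment at 0.05. The fit had 2 residual and 5.32 prior degrees of freedom. Unadjusted and adjusted p-values of single genes are from this moderated limma test and 2-sided. A descriptive rule counted probe sets at least 2-fold apart whose arrays did not overlap between groups.

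A total of 24 gene lists, the comparison and the rule for named genes were fixed before the data were examined. Lists with at least 5 kept members (20) were tested with limma's camera at a preset inter-gene correlation of 0.01. The same test with an estimated correlation, under which no list was called, and fry were alternatives. The camera test asks whether a list differs from other genes; fry asks whether its genes move one way. The rule named Calcr, 15 genes per direction with the smallest limma p among those whose arrays did not overlap (since none passed the threshold), up to 4 members per list with the smallest p, and a fixed set of 15 myogenic, Notch, cell cycle and immediate early genes. Other genes are given as examples of a list. Further lists written later are described as such where they appear.

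The steps were tested on simulated arrays with 200 of 22519 probe sets changed in the comparison of cKO and control, 2 arrays a group, over 5 runs. With noise alone, of the size left after the replicate numbers were fitted, limma recovered 32.5% of 2-fold, 96.7% of 4-fold and 100% of 8-fold changes. When the differences seen between replicate numbers were added, it recovered 1.49%, 17.9% and 58.5%. For lists, camera called 0 lists over 20 runs of 20 unchanged lists among 10140 genes, and called a cell cycle list shifted by 0.3 in 19 of 20 runs; genes were independent in this simulation, so it says nothing of correlated lists.

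Alternatives were quantile normalization, median centring, a pseudocount of 32, no filter, a stricter filter at the 75th percentile, eBayes without a trend, the replicate number as a block, only probe sets without a suffix, leaving out each array, the mean over a gene's probe sets, and a threshold of unadjusted p under 0.05 with a 2-fold difference. Where an array was left out, the lone sample of its group was assumed to vary like the other group. Leaving out the probe sets that differed by replicate number, and leaving Calcr out of the quiescent list, were added after the data were seen.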

Results

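Gene expression was measured in muscle satellite cells, the resident stem cells of skeletal muscle, taken straight from mouse muscle without culture. The calcitonin receptor gene Calcr, which encodes a G protein-coupled receptor, was deleted in satellite cells with a tamoxifen-dependent Cre driven from the Pax7 locus, and recombined cells carried YFP. The mice were 10 weeks old, and YFP-positive cells were sorted 2 weeks after tamoxifen. The comparison asks which transcripts differ between Calcr conditional knockout (cKO) cells and control cells with intact Calcr. Each group held 2 biological replicates, on 1 array each, so 4 arrays were compared and this number limits the precision. The values were MAS5 signals of 45101 probe sets. Median signals were 70.4 and 64.3 for control replicates 1 and 2, and 68.8 and 57.8 for cKO replicates 1 and 2. No values were identical between arrays. The 3'/5' signal ratio of the Gapdh control probe sets ran from 1.54 to 1.71, highest on cKO replicate 2.

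Calcr itself was lower in the cKO cells. Its only probe set read 1346 ± 110 (SD, n = 2) in control cells and 626 ± 82.0 (SD, n = 2) in cKO cells, a 2.15-fold difference, and both cKO arrays lay below both control arrays. The log2 difference was -1.11 with an SE of 0.25. As a single gene planned before the data were examined, Calcr had an unadjusted limma p of 0.00292. It did not pass over all probe sets, where its adjusted limma p was 0.99999, as was the smallest of any probe set. With 2 samples a group, the smallest 2-sided p of an exact permutation test is 0.333. A signal of 626 remained in cKO cells, and where the probe set lies relative to the deleted part of Calcr is not given in the sources used here, so the probe set may or may not read the deleted part. The lower signal goes in the direction of the labels.

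Across the transcriptome, no probe set passed the test, and the genes nearest to the threshold, with arrays that did not overlap, are given as values. Higher in cKO on both arrays were Dlk1, an imprinted gene of the Delta-like family, at 405 ± 160 against 1162 ± 138 (SD, n = 2), and Mrpl33, a mitochondrial ribosomal protein gene, at 627 ± 139 against 1590 ± 175 (SD, n = 2). Lower in cKO were Chrdl2, a BMP antagonist gene, at 1543 ± 769 against 284 ± 272 (SD, n = 2), and Igfbp4, which encodes an IGF-binding protein, at 4805 ± 395 against 2597 ± 662 (SD, n = 2). All 6 kept probe sets of Igfbp4 and both of Dlk1 had the same sign. Of 22519 probe sets tested with limma, 0 had an adjusted p under 0.05. At an unadjusted p under 0.05 there were 163, of which 49 were higher and 114 lower, while 1126 would be reached by chance. This fit has no term for the replicate number, so differences between the numbers count as noise in it. In the simulation with such differences it recovered 17.9% of 4-fold changes, so the lack of calls does not show that genotype has no effect. A total of 27 probe sets were at least 2-fold higher in cKO without overlap of the arrays and 96 at least 2-fold lower. That balance followed the scaling: after quantile normalization the counts were 50 higher and 64 lower, and with arrays centred on their median 45 and 72. At an unadjusted limma p under 0.05 they became 85 higher and 87 lower, and 71 and 89. Pooling both directions, cKO and control arrays did not overlap in 21.4% of probe sets, against 33.3% by chance. Splitting the same arrays by replicate number instead of genotype gave 521 probe sets with an adjusted p under 0.05, and 1292 at least 2-fold apart without overlap. The remaining split, control 1 with cKO 2 against control 2 with cKO 1, gave 0 and 326. It gave 908 at an unadjusted limma p under 0.05, and 33.9% of probe sets without overlap. The genotype split thus had the smallest counts at an unadjusted p, without overlap and by the 2-fold rule.

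The other genes nearest to the threshold covered several functions, and none had an adjusted limma p under 0.05. On the higher side were genes of cell division: Mki67 at 1.65-fold, the chromosomal passenger gene Birc5 at 2.0-fold, the mitotic kinase gene Pbk at 1.93-fold and Gins1, a replication complex gene, at 2.60-fold. Bdnf (2.0-fold), Sema5a (2.41-fold), Dcx (2.38-fold) and Nkain2 (2.62-fold), which are best known from neurons, were also higher in cKO, with Nkain2 at 119 and 50.6 in control against 151 and 277. Sema5a, Dcx and Gins1 were dim in control cells (46.7, 48.2 and 46.0, below the filter signal of 63.9), so their folds are uncertain. The list was completed by the amino acid transaminase gene Bcat1 (1.97-fold), the transcription factor IID gene Taf6 (1.89-fold), Rgs3 (1.93-fold), a regulator of G protein signalling, Col1a2 (1.85-fold) and Art3 (1.69-fold). On the lower side were genes of secreted signals: the chemokine genes Ccl2, at 1146 ± 54.7 against 533 ± 36.3 (SD, n = 2), and Cxcl2 (1.93-fold lower). Retnla read 240 and 662 in control against 150 and 106 in cKO, and its log2 difference of -1.65 was -0.93 without control replicate 2, the array on which Cd74 and H2-Aa of the leukocyte list were brightest. The prostaglandin transporter gene Slco2a1 was 1.94-fold lower, the proprotein convertase gene Pcsk5 2.72-fold lower, the sialidase gene Neu2 2.37-fold lower and Mpzl2 2.41-fold lower. Ptpn2 (1.53-fold), Cdc42bpg (1.89-fold) and Eif4g2 (1.31-fold) were lower by less, and only 3 of the 5 kept probe sets of Eif4g2 had that sign. Ilkap, a phosphatase gene, read 4276 and 5732 in control against 2013 and 805 in cKO on its brightest probe set, while its other kept probe set read 780 ± 95.7 and 711 ± 13.8 (SD, n = 2).

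**Figure D1:**
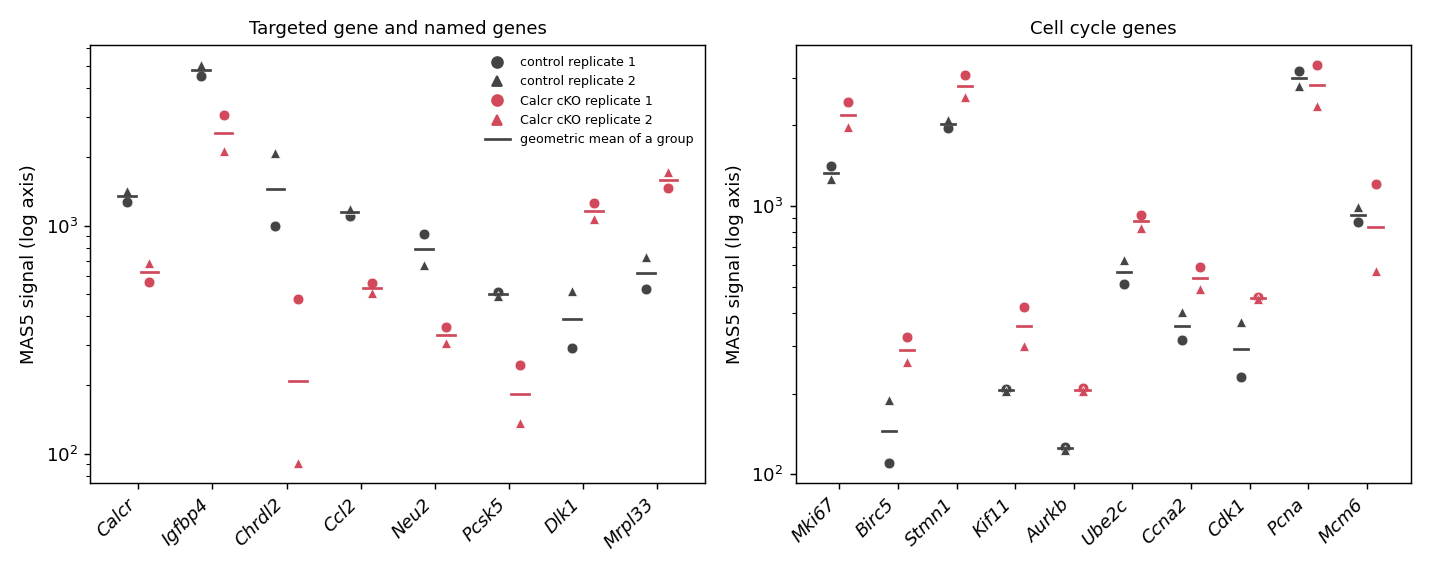
MAS5 signal (log axis) of 18 genes on each of the 4 arrays, with control in grey, Calcr cKO in red, replicate 1 as circles, replicate 2 as triangles and bars for the geometric mean of a group. Calcr lies at 568 and 684 in cKO against 1268 and 1424 in control, and Mki67 at 1971 and 2427 against 1257 and 1404, while Pcna and Mcm6 overlap between the groups.

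Genes of the cell cycle were higher in cKO as a set. Of 42 measured members of the cell cycle list, 34 were higher in cKO and 8 lower; 22 had both cKO arrays above both control arrays, and 0 had both below. The median log2 difference was 0.34, and limma's camera test with its preset correlation of 0.01 gave an adjusted p of 6.2e-13 over 20 lists. With a correlation estimated from the data the call was lost (adjusted p = 0.768). Mki67, the proliferation antigen, read 1331 ± 104 in control and 2199 ± 323 in cKO (SD, n = 2). Stmn1, a microtubule regulator, read 2022 ± 98.3 and 2804 ± 375, and the spindle motor gene Kif11 206 ± 2.26 and 361 ± 85.8 (SD, n = 2). Other members were Aurkb, a mitotic kinase gene (1.65-fold higher), Ube2c, of the anaphase-promoting machinery (1.54-fold), and cyclin A2 gene Ccna2 (1.51-fold). Relative to the median gene, the list was higher by 0.44 between the arrays numbered 1 and by 0.45 between the arrays numbered 2. Both values were at the 100th percentile of 10000 random lists matched on expression. Those lists were drawn gene by gene and hold no correlation between members, so a list whose genes vary together can reach an extreme. The muscle fibre list, which was not called, lay at percentiles 0 and 100 in the same comparisons. Splitting the arrays by replicate number, the cell cycle list's median differed by 0.04 (camera adjusted p = 0.743). Between control 1 with cKO 2 and control 2 with cKO 1 it differed by 0.18 (camera adjusted p = 0.339). No single member passed over all genes or adjusted over the list alone (smallest adjusted p = 0.419). Ccnd1 overlapped between the groups (log2 difference -0.33).

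Transcripts tied to the quiescent satellite cell were slightly lower in cKO as a set. Of 31 members, 20 were lower and 11 higher, with a median log2 difference of -0.14 (camera adjusted p = 0.0274, and adjusted p = 0.768 with an estimated correlation). The call was also lost with arrays centred on their median (median -0.09, adjusted p = 0.052), without a filter (adjusted p = 0.169), without an intensity trend (adjusted p = 0.290), with the mean over probe sets (adjusted p = 0.0708) and with only unsuffixed probe sets (median -0.03, adjusted p = 0.434). After quantile normalization the median was -0.08 (adjusted p = 0.0263). Between the arrays numbered 1, 20 of 31 members were higher in cKO (median 0.03), and between those numbered 2, 8 were (median -0.30). Relative to the median gene these medians were -0.06 and -0.11. The members with the smallest limma p were Igfbp4, Calcr, Chrdl2 and the Notch target Hey1, and Hey1 was higher, at 1622 ± 247 against 2070 ± 326 (SD, n = 2). Without Calcr, the targeted gene, the adjusted p was 0.0856. Leaving out control replicate 2 turned the median to 0.07 (adjusted p = 0.930), and leaving out cKO replicate 1 gave -0.16 (adjusted p = 0.178). Without control replicate 1 the median was -0.37 (adjusted p = 8.08e-05), and without cKO replicate 2 it was -0.12 (adjusted p = 0.000309). Adjusted over the list alone, 0 members passed, with a smallest adjusted p of 0.052. Pax7, the satellite cell transcription factor, read 2983 ± 939 in control and 2302 ± 187 in cKO (SD, n = 2). Myf5 read 2515 ± 688 and 2361 ± 682 (SD, n = 2). Both overlapped between the groups, as did Notch3 (log2 difference -0.16) and Heyl (-0.46). The cyclin-dependent kinase inhibitor genes Cdkn1b and Cdkn1c differed by 0.11 and 0.06 on the log2 scale.

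Myogenic commitment genes were not called as a set: 12 of 22 members were higher and 10 lower (median log2 difference 0.04, camera adjusted p = 0.422). Myod1, the commitment factor, read 1281 ± 127 in control and 975 ± 191 in cKO (SD, n = 2), and Myog, the differentiation factor, 2262 ± 301 and 2399 ± 375 (SD, n = 2). The agrin receptor complex gene Musk was lower on both cKO arrays (log2 difference -0.53). Chrna1 and Myh3 were higher on both (0.45 and 0.47). None of these passed.

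Pathways known to act in satellite cell quiescence gave no call. The Notch list had 12 of 19 members higher and a median of 0.11 on the log2 scale (camera adjusted p = 0.279), with Dll1 higher (0.39) and Rbpj and Maml1 lower (-0.35 and -0.25). Its target Col5a1 differed by 0.12. For targets and parts of the cAMP pathway, on which many calcitonin receptor signals run, the median over 32 members was -0.04 (adjusted p = 0.420). Nr4a2 (0.65) and Nr4a3 (0.31) were higher on both cKO arrays, and Pde10a overlapped between the groups (-1.08). YAP and TEAD targets had a median of -0.02 over 21 members (camera adjusted p = 0.469). Ccn1 was at 0.27, Ccn2 at -0.23, Axl at -0.47, Yap1 at -0.29, Igfbp3 at 0.43 and Amotl1 at 0.53. Other kept probe sets of Ccn1 were at 0.12, -0.16 and -0.21, and that of Yap1 at 0.12. Immediate early and dissociation genes were bright on every array (median signal 3980 to 4612) and were not called (median -0.02 over 34 members, adjusted p = 0.680). Fos read 5725 ± 122 and 6022 ± 700 (SD, n = 2). Within that list Klf4 and Atf3 were higher on both cKO arrays (0.28 and 0.22) and Fosl1 and Btg1 lower (-0.40 and -0.14). The other kept probe set of Klf4 was at -0.03.

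Extracellular matrix genes had 22 of 37 members higher (median 0.07, adjusted p = 0.260), with Thbs2 (-0.86) and Lox (-0.85) lower on both cKO arrays, Loxl1 overlapping (-0.81), and Col1a2 higher. The interferon list was not called (median -0.16, adjusted p = 0.356), nor were p53 targets (0.01, adjusted p = 0.279), oxidative phosphorylation (-0.01, adjusted p = 0.279) and glycolysis (-0.17, adjusted p = 0.0856). Examples were Isg20 (-0.61) and Ifit2 (0.61), Zmat3 (0.56) and Ccng1 (0.42), Ndufa5 (0.21), and Pgam1 (-0.37). Genes of the unfolded protein response were called lower, with 18 of 23 members lower and a median of -0.16 (adjusted p = 0.0427, and adjusted p = 0.768 with an estimated correlation). Xbp1 (-0.35), Dnajc3 (-0.36), Chac1 (-0.54) and Calr (-0.16) were lower on both cKO arrays. Other kept probe sets of Dnajc3 differed by 0.20, 0.06, -0.08 and -0.29. The difference lay between the arrays numbered 2 (relative median -0.27), against 0.12 between those numbered 1, and the pooled median turned to 0.0025 without cKO replicate 2 (adjusted p = 0.677) and to 0.07 without control replicate 2 (adjusted p = 0.729). It was -0.29 without control replicate 1 and without cKO replicate 1 (adjusted p = 0.00148 and 0.0191). The call was also lost with quantile normalization (adjusted p = 0.0839) and with arrays centred on their median (adjusted p = 0.116). Camera's adjusted p was 0.169 without a filter and 0.338 without an intensity trend. It was 0.191 with only unsuffixed probe sets and 0.127 with the mean over probe sets. Leaving out probe sets that differ by replicate number gave 0.0505. Ribosomal protein genes were called too, with 22 of 25 lower, yet with a median of only -0.05 (adjusted p = 0.0440, and adjusted p = 0.828 with an estimated correlation). The median over all genes was -0.04, and the list lay at the 52.5th percentile of 10000 random lists matched on expression. With arrays centred on their median the list's median was 0.01, and the call was lost (adjusted p = 0.402). Camera's call was also lost with quantile normalization (adjusted p = 0.255), without a filter (0.304) and without an intensity trend (0.380). A replicate block, the stricter filter and the mean over probe sets gave adjusted p = 0.0700, 0.0508 and 0.0561. With only unsuffixed probe sets it held (median -0.32, adjusted p = 0.0300). Without control replicate 2 the median was 0.05 (adjusted p = 0.523), and without cKO replicate 1 the test's direction turned (median -0.03, adjusted p = 0.911). Without control replicate 1 and without cKO replicate 2 the medians were -0.16 and -0.08 (adjusted p = 6.47e-06 and 0.000531). For the cAMP, YAP, immediate early, oxidative phosphorylation and fibro-adipogenic lists, camera's direction was up while the median was below 0, and these 5 medians changed sign when arrays were centred. For the extracellular matrix and muscle fibre lists the mean was below 0 (-0.01 and -0.07) while the median and the direction of the test were above it.

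**Figure D2:**
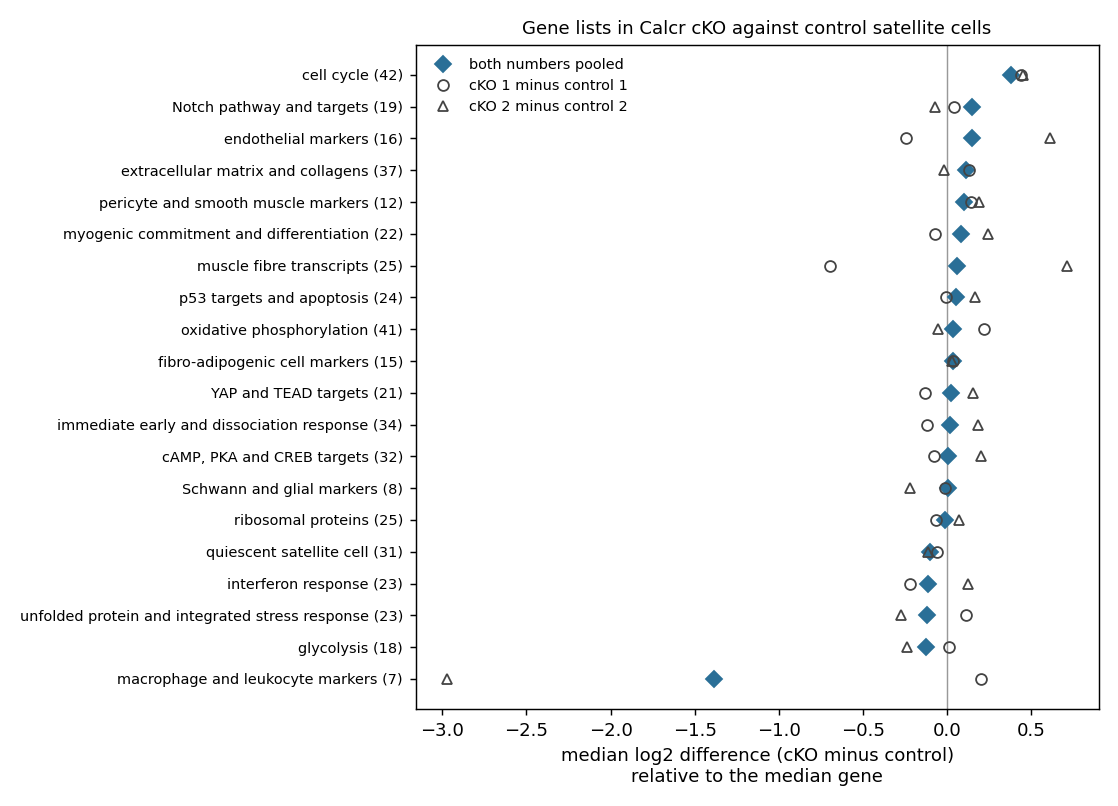
Median log2 difference of each of the 20 tested gene lists (number of measured members in parentheses), cKO minus control and relative to the median gene, pooled (diamonds), between the arrays numbered 1 (circles) and between those numbered 2 (triangles). The cell cycle list lies at 0.44 and 0.45 in the separate comparisons, while the leukocyte list lies at 0.21 and -2.97 and the muscle fibre list at -0.70 and 0.72.

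Endothelial transcripts, and part of the pericyte transcripts, differed strongly by replicate number in both genotypes. The endothelial list was at a median signal of 783 on control replicate 1 and 812 on cKO replicate 1, against 69.6 and 94.2 on replicates 2, an 11.1-fold median difference, and 16 of 16 measured members were at least 2-fold higher on replicate 1 in both groups. Cdh5 (VE-cadherin) read 1044 and 1060 on replicates 1 and 79.7 and 110 on replicates 2. Of pericyte and smooth muscle markers, 7 of 12 did the same, with a 2.86-fold median difference. Kcnj8, for example, read 502 and 601 against 52.3 and 148. Neither list was called between genotypes (camera adjusted p = 0.469 and 0.405). In all, 712 probe sets were at least 2-fold apart by number in both groups, 645 of them higher on replicate 1. Over the kept probe sets, arrays of the same number correlated at 0.964 and 0.946, and arrays of the same genotype at 0.900 and 0.913. These correlations are across probe sets, which are not independent replicates.

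Leukocyte transcripts were lower in cKO as a set, with 6 of 7 measured members lower and a median log2 difference of -1.43 (camera adjusted p = 0.000473, and adjusted p = 0.768 with an estimated correlation). Only 7 of 22 listed members passed the filter, and without a filter the median was -0.89 (adjusted p = 0.000578). The difference came from the arrays numbered 2: the median was -3.16 between them and 0.30 between those numbered 1. The antigen presentation genes Cd74 and H2-Aa read 451 and 433 on control replicate 2, and 111 or less on the other arrays. Without control replicate 2 the median was -0.35 (adjusted p = 0.215), and without cKO replicate 2 it was -0.60 (adjusted p = 0.0523). Without control replicate 1 and without cKO replicate 1 it was -2.03 and -2.00 (adjusted p = 1.86e-05 and 5.66e-07). Laptm5, a lysosomal gene of blood cells, was lower on both cKO arrays (320 ± 10.3 against 55.1 ± 44.5, SD, n = 2) on its single probe set above the filter. It was the 1 member of the tested lists that passed limma adjusted over the list alone (adjusted p = 0.0153), while 0 passed over all genes. Lyz2 read 432 and 463 in control, 532 on cKO replicate 1 and 50.7 on cKO replicate 2, and Cd68 was not lower (log2 difference 0.40). Fcer1g read 142 ± 47.8 and 72.5 ± 25 (SD, n = 2).

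The remaining lists gave no call. Fibro-adipogenic markers had 7 of 15 members higher (adjusted p = 0.285), led by Col1a2 and Dpep1, with Dpt and Gsn lower (-0.31 and -0.18). Schwann and glial markers had 3 of 8 higher (adjusted p = 0.420), with Cadm4 lower on both cKO arrays (-0.78). Muscle fibre transcripts had 13 of 25 higher (adjusted p = 0.967), and their relative medians of -0.70 between arrays numbered 1 and 0.72 between those numbered 2 had opposite signs. Actn3 was lower in both comparisons (log2 difference -0.68). Tendon and red cell lists had 3 measured members each, too few for the test, with medians of -0.19 and -0.20. Xist read 3904 to 4902 on its brightest probe set and 0 of the Y-linked genes passed the filter, on arrays of either genotype.

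**Figure D3:**
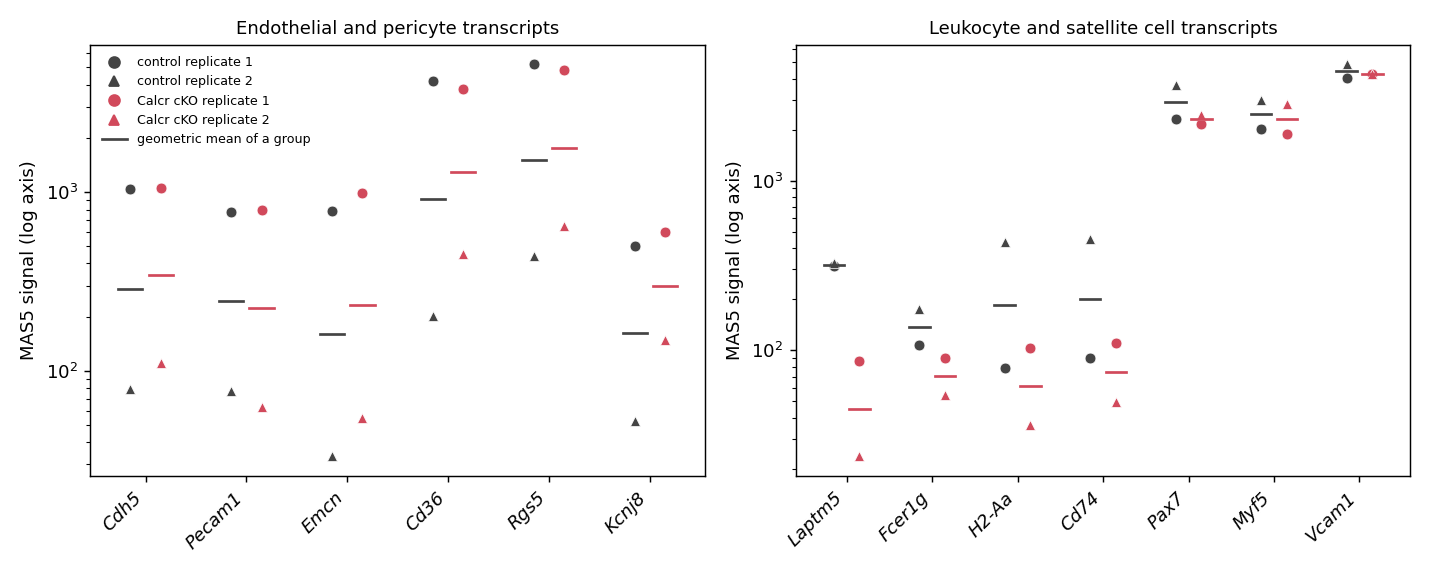
MAS5 signal (log axis) of 13 endothelial, pericyte, leukocyte and satellite cell transcripts on each array, with control in grey, Calcr cKO in red, replicate 1 as circles, replicate 2 as triangles and bars for the geometric mean of a group. Cdh5 reads 1044 and 1060 on the replicates 1 and 79.7 and 110 on the replicates 2, H2-Aa is highest on control replicate 2 at 433, and Vcam1 lies between 4006 and 4861 on all 4 arrays.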

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

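The lower signal of Calcr kept its sign and an unadjusted limma p under 0.05 under every alternative run, with log2 differences from -0.97 to -1.24 when arrays were left out. The cell cycle list stayed called by camera in every alternative run except an estimated correlation and fry (adjusted p = 0.768 and 0.988), with medians from 0.23 (stricter filter) to 0.48 (without control replicate 2). Single probe sets depended on the setting: 0 passed in the main analysis, 81 at an unadjusted p under 0.05 with a 2-fold difference, and 0 to 5 with 1 array left out (1 without control replicate 1, 5 without cKO replicate 1). Probe sets at least 2-fold apart without overlap numbered 48 with a pseudocount of 32, 2727 without a filter, 22 with the stricter filter and 507 to 1103 with 1 array left out, where a lone array overlaps less easily, against 123. They numbered 123 too with the probe sets that differ by replicate number left out.

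The labels do not say that a replicate number marks a shared litter or day, and there are only 2 numbers. Deviations from the group means correlated at 0.43 between same-numbered samples. With the replicate number as a block, 5 probe sets passed limma. They were those of Slc15a2, Laptm5, Pisd-ps3 and Ilkap (lower in cKO) and 1 with no gene name (log2 difference 4.43). Slc15a2 overlapped between the groups, at 2168 and 56.4 in control against 558 and 1.13 in cKO. The unnamed probe set read 5.79 on control replicate 2. Signals this low make the size of both log2 differences uncertain. In this fit 4 lists were called, and the log2 difference of Calcr was -1.11 again (adjusted p = 0.704). Over genes, Chrdl2 (adjusted p = 0.00127) and Igfbp4 (adjusted p = 0.0128) passed too, with Laptm5 and Ilkap. In the simulation with differences between numbers, the fit with the block recovered 27.8%, 95.8% and 100% of 2-fold, 4-fold and 8-fold changes, with a mean of 11.8 false calls a run.

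Against 5 called gene lists, there were 3 with quantile normalization, with the mean over probe sets, or with probe sets that differ by number left out. There were 2 with arrays centred, without a filter, without an intensity trend, with only unsuffixed probe sets, or without Calcr in the quiescent list. With an estimated correlation and with fry there were 0. With 1 array left out there were 7 to 11. Leaving out an array leaves its group with only 1 replicate number, so differences between the numbers enter the comparison of genotypes. The endothelial list followed this, with medians of 1.79 without control replicate 1 and 1.73 without cKO replicate 2. Its medians were -1.71 without control replicate 2 and -1.42 without cKO replicate 1. Lists called only in these fits therefore cannot be read as effects of genotype. How much of each call the numbers account for was not tested. Lists that passed in the other direction with 1 array left out, or were called before and turned direction, had medians from -1.71 to 1.79 (endothelial), -0.51 to 0.33 (muscle fibre), -0.48 to 0.96 (pericyte), -0.48 to 0.27 (interferon), -0.11 to 0.13 (immediate early) and -0.16 to 0.049 (ribosomal proteins). Under the stricter filter and with unsuffixed probe sets the leukocyte list had too few members for a value. Of 238 values of uncalled lists under alternatives, 27 passed, 8 of them in the other direction, and 31 in all had the other test direction. Of 1586 values of 118 named genes, 6 passed and 46 had the other sign. Dim probe sets limit the count by size, since 2727 met that rule without the filter.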

Other observations

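The lists in this part were added after the data were first examined, the second endothelial list and the calcitonin family list before their own values were seen. All rules for judging explanations were written after the results were seen. The quantile, median-centred and left-out array settings that some of these rules use had been planned as alternatives. Within the cell cycle list, the mitotic and the replication genes differed in pattern. The list was cut into these parts after its values had been seen, so the cut itself may have favoured the contrast. All 21 measured genes of the mitotic part were higher in cKO, 19 of them on both cKO arrays against both control arrays, with a median log2 difference of 0.54. Relative to the median gene this was 0.57 between the arrays numbered 1 and 0.53 between those numbered 2. Examples are Cdk1, at 230 and 370 in control against 458 and 451 in cKO, Aurka, at 67.8 and 82.6 against 118 and 137, and Tpx2, at 115 and 173 against 230 and 211. Of the DNA replication part, 9 of 14 were higher (median 0.14), with relative medians of 0.41 and -0.03. Mcm6 read 1206 on cKO replicate 1 and 574 on cKO replicate 2, around control values of 870 and 986. The difference between the parts was not tested.

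Chemokine and cytokine genes, picked after Ccl2 and Cxcl2 had stood out, were lower in 11 of 12 cases (median log2 difference -0.51, and -0.40 after quantile normalization, which kept 13 members), 6 of them on both cKO arrays against both control arrays. Without those 2 genes, 9 of 10 were lower (median -0.39). The leukocyte list was lower between the arrays numbered 2 only, while 11 of these 12 genes were lower within both numbers. Between the arrays numbered 2, however, the median gene was itself at -0.19 on the log2 scale. Csf1 (-0.04), Cxcl1 (-0.05), Cxcl10 (-0.06) and Ccl11 (-0.13) lay above it there. Relative to the median gene, the chemokine list was at -0.49 between the arrays numbered 1 and -0.29 between those numbered 2. Ccl7 read 489 and 592 in control and 366 and 313 in cKO, and Lif 308 and 739 against 142 and 338. The exception was Cxcl12, which followed the replicate number (1880 and 1834 on replicates 1, 290 and 400 on replicates 2). Of 15 imprinted growth genes, 8 were higher and 7 lower, and Dlk1 was furthest apart. Its neighbours in the same imprinted cluster Meg3, Rian and Mirg differed by -0.13, -0.04 and -0.14 on the log2 scale on their brightest probe sets, a sign shared by only 1 of 11 kept probe sets of Meg3 and 1 of 4 of Rian. Of the calcitonin receptor's relatives, Calcrl read 625 and 336 in control against 379 and 434 in cKO, and the accessory protein gene Ramp2 653 and 926 against 855 and 1044. Neither separated the groups.

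Endothelial transcripts, and part of the pericyte transcripts, were far higher on both replicates numbered 1. Array scaling is argued against: the median log2 difference between numbers was 3.37 after quantile normalization. A second list of 20 endothelial genes, of which 1 measured member (Tek) is also in the quiescent satellite cell list, had 15 of its 19 measured members at least 2-fold higher on replicate 1 in both groups, the brightest being Epas1 (4214 and 4398 against 1364 and 1765) and Igfbp7 (2697 and 3023 against 959 and 1091). A candidate explanation is therefore endothelial cells or their RNA in those preparations, although a gate on YFP should remove cells without Pax7-driven recombination. The design names no difference between the numbers, and no biological explanation was tested.

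The cell cycle list was higher in cKO. Array scaling is argued against by its median of 0.40 with arrays centred on their median, and a single replicate number by the smaller of its relative shifts within a number, 0.44. Dividing cells of another type may still contribute. Of 6 lists for other cell types the highest of the smaller shifts within a number was 0.14 (pericyte), below the shift of the cell cycle list. A small share of dividing cells could be hidden under those markers, however. A gate on YFP should remove such cells, but the endothelial list read 783 and 812 on the replicates numbered 1. The gate therefore does not exclude dividing cells of another type. An effect of Calcr loss on satellite cells stays open and cannot be told apart from such cells here. With an estimated correlation the list was not called, so the pattern remains a hypothesis.

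The leukocyte list was lower in cKO, with a median of -3.16 on the log2 scale between the arrays numbered 2 and 0.30 between those numbered 1. Camera called it with the preset correlation (adjusted p = 0.000473) but not with an estimated correlation (adjusted p = 0.768). Without control replicate 2 the median was -0.35 instead of -1.43, and without cKO replicate 2 it was -0.60, and each time the list was no longer called (adjusted p = 0.215 and 0.0523). Leukocytes or their RNA in the sort of control replicate 2, where Cd74, H2-Aa and C1qb were brightest (451, 433 and 425), may contribute. Both medians met the same rule, written after they were seen, so this cannot be told apart from fewer leukocytes in cKO replicate 2. A gate on YFP should remove such cells, but endothelial transcripts were bright on the replicates numbered 1, so the gate does not decide this. The first source does not account for the brightest probe sets of Laptm5 and Lyz2. These were at most 0.10 higher (log2) on control replicate 2 than on control replicate 1. Dim Laptm5 probe sets, below the filter, read 39.4, 35.5, 12.8 and 1.34 on control replicate 1. On control replicate 2 they read 68.4, 62.5, 8.47 and 8.82, so for Laptm5 this rests on its single probe set above the filter. An effect of genotype stays open for Laptm5, which was low on both cKO arrays on that probe set. It passed limma adjusted over the list alone (adjusted p = 0.0153) but not over all genes. The adjustment over the list was made within each list, with no correction over the lists, so it is weak support.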
